A study of Mus musculus with 6 samples.

How the data were processed

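The series holds RNA sequencing of 6 libraries of the mouse mammary carcinoma line 4T1, 3 labelled control and 3 labelled as treated with corticosterone. Groups were taken from the treatment field of the labels and replicate numbers from the sample titles. Per the labels' protocols, total RNA was the starting material, and both a column kit and TRIzol are named for its extraction. The deposited table holds 28154 genes with a count and an FPKM value per library, gene coordinates, and annotation terms. The counts are, per the file headers, counts per gene and library. They are whole numbers that the authors did not normalize, and the counter is not given in the sources used here. The FPKM values were deposited by the authors in the same table, per the file headers, as fragments per kilobase of transcript scaled to library depth. The aligner, the strandedness, the read layout, the dose and the time of treatment are not given in the sources used here. The labels name the human build GRCh38, but all 28154 gene identifiers are mouse identifiers (ENSMUSG). Of these 28086 were found in GENCODE release M21 (mouse build GRCm38), 90.4% of them with identical coordinates, and coordinates in the text are those of the deposited table. No value column was left unmapped to a sample.

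Before the data were examined, the samples, the tests, the gene lists, the naming rule for genes and the alternatives were fixed. The plan assumed FPKM, with limma on log2(FPKM + 1) as the test, and named edgeR's quasi-likelihood test on counts as the main test if the file also held counts. The file held them, so edgeR was used and limma became an alternative. Library totals (in M counts) were 63.4, 65.4 and 65.9 for control replicates 1, 2 and 3 and 62.2, 66.2 and 64.6 for corticosterone replicates 1, 2 and 3. A floor of 3 counts was thus 4.53e-06 to 4.83e-06% of a library.

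Counts were scaled by the trimmed mean of M values (TMM) and filtered with filterByExpr (minimum count 10, minimum total count 15), which left 17283 genes. They were fitted in edgeR 4.0.16 (R 4.3.3) with group as the only factor, and p-values were adjusted by Benjamini-Hochberg over all tested genes. Genes with an adjusted p under 0.05 are said to have changed, risen or fallen. The biological coefficient of variation was 0.135. Between libraries of the same number, deviations from the group means were hardly related (Pearson r of 0.011, 0.038 and -0.088), so libraries were not paired. Library measures were compared by exact permutation of the 6 libraries, two-sided. Scores are means of log2 CPM over the tested members of a list.

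Of 32 fixed gene lists (728 genes, 702 in the table), 29 had at least 5 tested members. They were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the lists), and beside it with a correlation estimated from the data and with fry. Each list also has the number of members that changed and the number with an adjusted p under 0.05 when adjusted over the list alone. Annotation terms of the table with 10 to 300 tested genes were tested in the same way, over 4596 terms. Genes named were 10 fixed in advance, the 12 with the largest rise and the 12 with the largest fall among changed genes without overlap between groups and with a group mean of at least 5 FPKM, up to 4 members of each list by lowest p, and the 5 most abundant changed genes. Other genes named are said in the text to be chosen after their values were seen. Terms named were the 8 with the lowest p in each direction, skipping any that shared over 70% of its genes with a term already named. For genes with 0 counts in all control libraries the fold is a lower bound, with 3 counts put over the control group.

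Alternatives fixed in advance were limma with an intensity trend on log2(FPKM + 1), with FPKM of at least 1 in at least 3 libraries, its pseudocounts of 0.1 and 0.5, no filter, TPM scaling, quantile normalization, no intensity trend and robust empirical Bayes. The others were DESeq2 1.42.0, DESeq2 size factors in edgeR (the median ratio scaling), and edgeR with a mean FPKM of at least 5 or with no low count filter. Further ones were the replicate block, each library left out in turn, and stricter and looser thresholds. Leaving out a library also lowers the power of the test, so calls can be lost for that reason alone. Chosen after seeing the data were limma-voom with library weights, edgeR offsets that take out each library's trend on transcript GC content and length (known for 99.9% of tested genes), the ribosomal protein score of each library as a covariate, list counts without corticosterone replicate 2, and terms with an estimated correlation.

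The pipeline was tested on simulated data with 17283 genes, of which 200 were changed. It called 58% of 1.5-fold and 67% of 2-fold changes with 4 false calls, and limma called 69% of 2-fold changes with 6 false calls. A list shifted by 0.4 on the log2 scale was found, and 0 of 26 lists without shared genes were called. Simulated genes varied independently, so this cannot show how often lists of genes that vary together are called falsely. With a GC trend put into 1 simulated library, 35% of 2-fold changes were called without offsets and 66.7% with them, with 1 false call. That trend was 0.5 on the log2 scale per SD of GC. The trends on GC and length fitted in the real libraries had SDs over genes of 0.0055 to 0.115, a size that the simulation did not cover. Tables were read with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and the R package for data tables (version 1.17.8), and figures drawn with matplotlib 3.10.9. No library was left out of the main test. Genes below the filter were left out of tests. Raw reads were not used here. Some genes that the naming rule covers are not reported here.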

Results

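The series measured gene expression by RNA sequencing in 4T1 cells, a mouse mammary carcinoma line that grows and spreads in syngeneic mice, after treatment with corticosterone, the main glucocorticoid of rodents. It holds 6 libraries, 3 from control cells and 3 from corticosterone-treated cells. The dose and the length of treatment are not given in the sources used here. The libraries held between 62175495 counts (corticosterone replicate 1) and 66249288 counts (corticosterone replicate 2), and between 22244 and 22683 genes had at least 1 count. The mean total did not differ between the groups beyond the spread of replicates (64.9 ± 1.34 M counts in controls and 64.3 ± 2.05 M counts with corticosterone, SD, n = 3; exact permutation test, two-sided p = 0.7, the smallest possible being 0.1). The first principal component, with 29.0% of the variance of log2 CPM (counts scaled to library depth), separated the groups, with corticosterone replicate 2 (9.17) closest to the controls and the other treated libraries at 29.6 and 38.5. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples.

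The comparison of treated with control cells asks which genes respond to corticosterone in 4T1 cells. Corticosterone raised known targets of the glucocorticoid receptor, with Per1, a repressor of the circadian clock, 3.37-fold higher and Tsc22d3, which encodes the anti-inflammatory protein GILZ, 2.94-fold higher. The list of the unfolded protein and integrated stress responses also rose, with a median log2 fold change of 0.40 over 30 genes. Of these, 16 passed. The list of receptor induced targets had a median of 0.18 over 35 tested genes, of which 10 passed. Of 30 inflammatory genes known to be repressed by glucocorticoids 10 fell, among them Mmp3 (stromelysin-1) by 1.40 on the log2 scale. The list of cholesterol synthesis and uptake fell (median -0.31), as did the interferon-stimulated and antigen presentation lists (medians of -0.35 and -0.21), although these last did not pass with an estimated correlation (camera, adjusted p = 0.273 and 0.178). In all, 487 of 17283 tested genes changed (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 234 higher and 253 lower.

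Of the 35 tested members of the list of glucocorticoid receptor induced targets, 10 rose and 25 did not pass, with 12 higher when adjusted over the list alone. The median log2 fold change of the list was 0.18, with 24 members above 0 and 11 below. The list ranked above other genes (camera, adjusted p = 1.03e-21), and 7 of the 10 calls held without each library in turn. Per1 (chromosome 11, 69095217 to 69109960, GRCm38) went from 19.7 ± 1.09 to 66.4 ± 4.32 CPM (SD, n = 3), a log2 fold change of 1.75 (SE 0.077; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.85e-05). Tsc22d3 (chromosome X, 140539528 to 140600659) went from 23.9 ± 1.10 to 70.1 ± 2.27 CPM, a log2 fold change of 1.55 (SE 0.065). Klf9, a Krüppel-like transcription factor, rose by 1.28, Sgk1, the serum and glucocorticoid regulated kinase, from 105 ± 6.80 to 210 ± 19.0 CPM, and Fkbp5, a co-chaperone of steroid receptors, by 0.77 on the log2 scale. These 5 calls held without each library in turn. Zbtb16 had too few counts to be tested, with 0 in the 3 control libraries and 12, 6 and 4 in the treated ones, which is at least 7.36-fold higher (floor of 3 counts over the control group). Dusp1, a MAP kinase phosphatase, had a log2 fold change of 0.22 that did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.254).

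Among 20 tested steroid receptors, chaperones and corticosteroid metabolism genes, 3 rose: Fkbp5 and the drug efflux transporters Abcb1a (1.43) and Abcb1b (0.78), which held without each library in turn. Hsp90aa1 (0.15) was the other higher member adjusted over the list alone, 4 in all, and 8 members rose and 2 fell without corticosterone replicate 2. The list passed (camera, adjusted p = 3.94e-05, and adjusted p = 0.049 with an estimated correlation). Transcripts of the receptors did not pass: Nr3c1, the glucocorticoid receptor, had a log2 fold change of 0.27 at 41.3 ± 4.07 CPM in controls (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.391, and 0.00949 without corticosterone replicate 2), and Nr3c2, the mineralocorticoid receptor, one of 0.06 at 0.599 ± 0.0871 CPM. Hsd11b1, which converts inactive 11-keto steroids to corticosterone, had a log2 fold change of 0.08, or -0.21 without corticosterone replicate 2, neither of which passed. Fkbp5, Abcb1a, Abcb1b, Dusp1, Nr3c2 and Hsd11b1 overlap genes on the opposite strand, and because strandedness is not given in the sources used here their counts are uncertain.

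**Figure D1:**
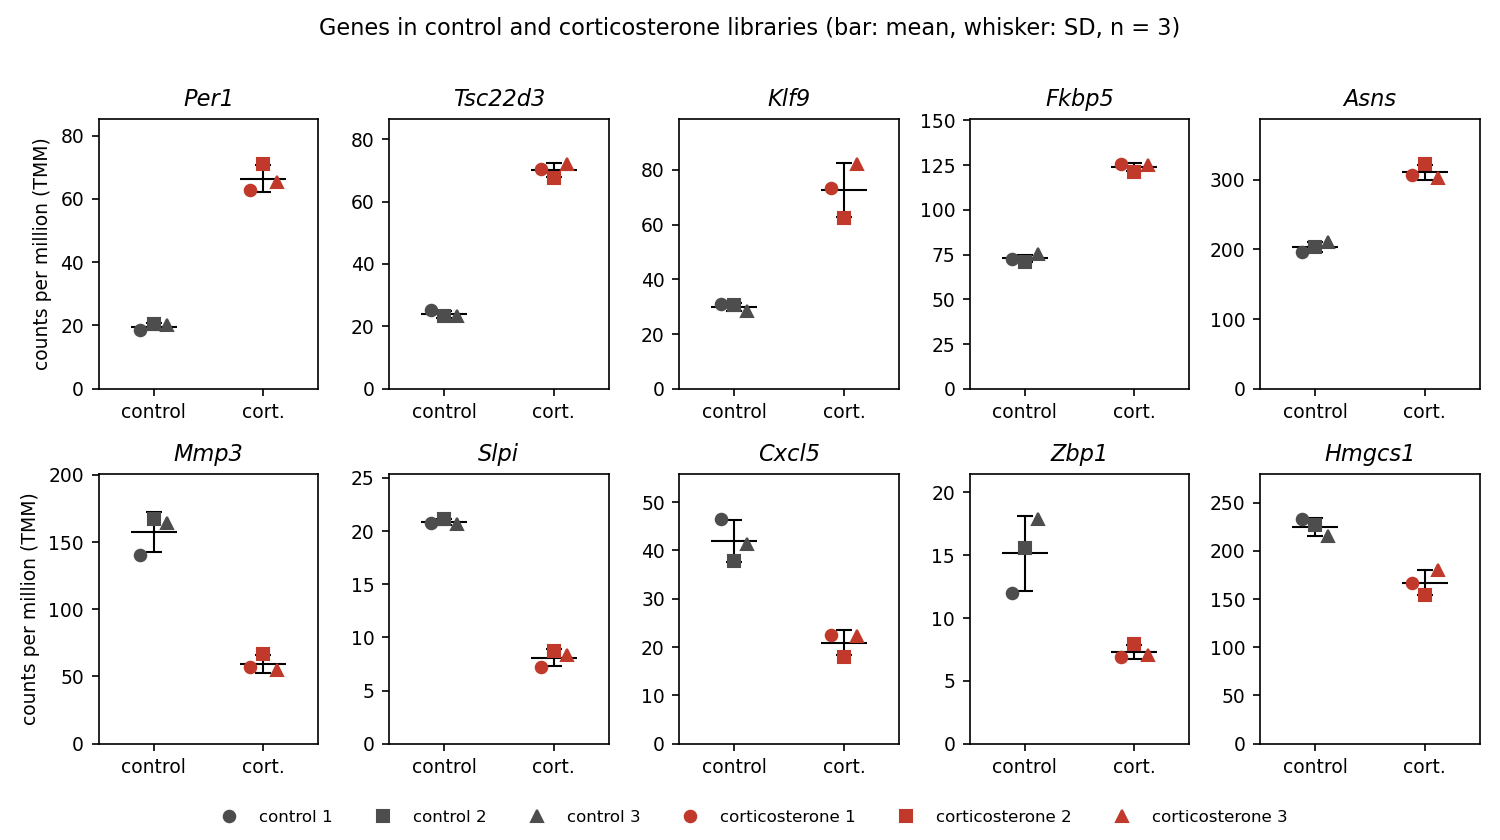
Expression in CPM (scaled by the trimmed mean of M values) of 10 genes in the 3 control and 3 corticosterone libraries. Points are libraries, bars group means and whiskers SDs, and each vertical axis starts at 0. In every panel the groups do not overlap, with Per1 rising from 19.7 to 66.4 and Mmp3 falling from 157 to 59.6 on average.

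The list of inflammatory genes known to be repressed by glucocorticoids held 30 tested members, of which 10 fell and 20 did not pass, with 15 lower when adjusted over the list alone (camera, adjusted p = 1.65e-14). Of the 10 calls 3 held without each library in turn. Mmp3 (chromosome 9, 7445822 to 7455975) went from 157 ± 14.7 to 59.6 ± 6.63 CPM, a log2 fold change of -1.40 (SE 0.098; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00078). The neutrophil chemokine Cxcl5 fell from 42.0 ± 4.39 to 20.9 ± 2.56 CPM, Mmp9 (gelatinase B) by 0.92 on the log2 scale and Csf3, which encodes the granulocyte growth factor G-CSF, by 0.68. The calls of Mmp3, Cxcl5 and Mmp9 held without each library in turn, and that of Csf3 was lost without control replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0558). Outside the list, the protease inhibitor Slpi fell by 1.37, Tslp, an epithelial cytokine, by 1.24 and Mmp10 (stromelysin-2) by 0.99. Spp1 (osteopontin), among the most abundant genes that changed, went from 950 to 575 CPM (log2 fold change -0.72).

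Of 30 tested interferon-stimulated genes, 7 fell and 23 did not pass, while 19 fell and 2 rose without corticosterone replicate 2. The mean log2 level of the list relative to controls was -0.20, 0.05 and 0.15 in control replicates 1, 2 and 3. It was -0.37, -0.30 and -0.40 in corticosterone replicates 1, 2 and 3, so the groups did not overlap but the controls spread widely. Adjusted over the list alone, 18 were lower and 1 higher, Oasl1 (0.28, chosen after its value was seen). Zbp1, a sensor of Z-form nucleic acids, fell by 1.05, Ifit3b by 0.73, Ifi44 by 0.66 and the guanylate-binding protein Gbp2 by 0.58. Outside the list, the interferon-induced GTPases Tgtp1 and Tgtp2 fell by 0.98 and 1.05. They are near-identical copies and overlap a gene on the opposite strand, so their separate values are uncertain. Ifitm2, which restricts viral entry and is also outside the list, fell by 0.83. Of 25 tested antigen presentation and immune checkpoint genes, 5 fell and 20 did not pass, with 13 lower adjusted over the list alone, while 16 fell and 1 rose without corticosterone replicate 2. They were Lgals9 (galectin-9, -0.82), H2-T23 (a non-classical class I molecule, -0.77), the immunoproteasome subunits Psmb9 (-0.79, chosen after its value was seen) and Psmb8 (-0.72), and Tapbp (tapasin, -0.40). Both lists passed (camera, adjusted p = 5.07e-14 and 7.76e-10). Neither passed with an estimated correlation (camera, adjusted p = 0.273 with an estimated correlation for the interferon list and adjusted p = 0.178 with an estimated correlation for antigen presentation). Each gene called here lost its call without control replicate 2 and without corticosterone replicate 1, and some also without control replicates 1 or 3 or corticosterone replicate 3, with adjusted p up to 0.154 (edgeR quasi-likelihood, Benjamini-Hochberg; Psmb9 without control replicate 2). Gbp2, H2-T23, Tapbp, Psmb8, Psmb9 and Oasl1 overlap genes on the opposite strand.

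All 30 members of the unfolded protein and integrated stress response list had positive log2 fold changes. Of these, 16 rose and 14 did not pass, and 27 were higher adjusted over the list alone (camera, adjusted p = 3.85e-38, and adjusted p = 0.0297 with an estimated correlation). Of the 16 calls 5 held without each library in turn, and 25 members rose without corticosterone replicate 2. Chac1, which degrades glutathione, rose by 0.80, Asns (asparagine synthetase) by 0.61, Herpud1, a factor of endoplasmic reticulum associated degradation, by 0.53 and the amino acid transporter Slc7a5 by 0.49, and these 4 calls were among the 5 that held. The chaperone Hspa5 (BiP), among the most abundant genes that changed, went from 1919 ± 72.1 to 2544 ± 48.9 CPM (log2 fold change 0.41), a call lost without control replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0586). Herpud1 overlaps a gene on the opposite strand.

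All 24 tested members of the cholesterol synthesis and uptake list had negative log2 fold changes. Of these, 11 fell and 13 did not pass, and 21 were lower adjusted over the list alone (camera, adjusted p = 9.4e-21, and adjusted p = 0.00813 with an estimated correlation). Of the 11 calls 0 held without each library in turn, and 20 members fell without corticosterone replicate 2. Hmgcs1, the enzyme that makes HMG-CoA, fell by 0.43, Acat2 by 0.42 and Cyp51 (lanosterol demethylase) by 0.39. Each of these 3 calls was lost without control replicate 2 and without corticosterone replicate 1, and those of Hmgcs1 and Acat2 also without control replicates 1 and 3, with adjusted p up to 0.108 (edgeR quasi-likelihood, Benjamini-Hochberg; Hmgcs1 without control replicate 2). Cyp51, Hmgcs1, Elovl6 and Acacb overlap genes on the opposite strand. In the fatty acid synthesis and oxidation list, the desaturase Fads2 was the 1 of 26 members that fell (-0.28), and Elovl6 (-0.25) and Fasn (-0.19) were the other members lower adjusted over the list alone, a total of 3, while Acacb (-0.49) did not pass and 8 members fell without corticosterone replicate 2. The list passed (camera, adjusted p = 0.0051), but not with an estimated correlation (camera, adjusted p = 0.121 with an estimated correlation), and the call of Fads2 was lost without each library but corticosterone replicate 2 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.182, without control replicate 2).

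**Figure D2:**
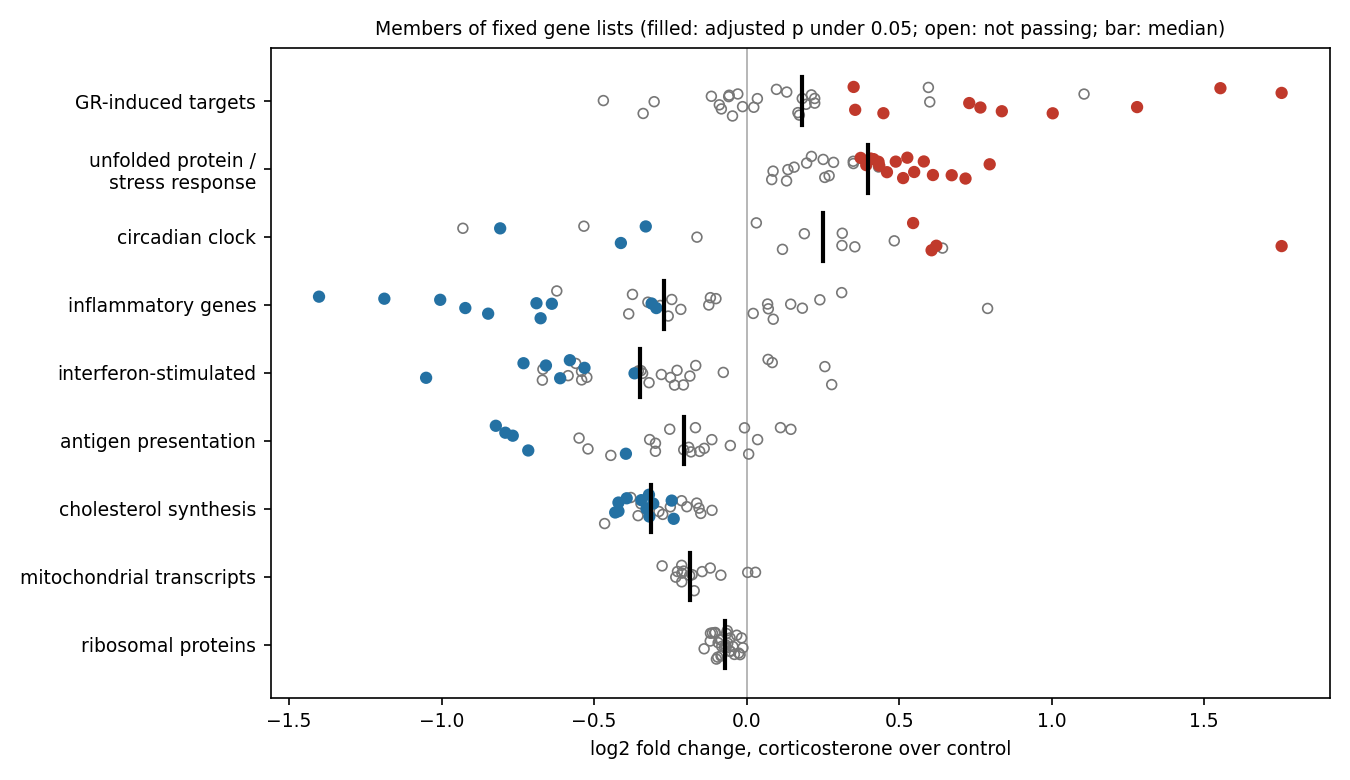
Log2 fold change (corticosterone over control) of each tested member of 9 gene lists. Each point is 1 gene, filled when its adjusted p is under 0.05 and open when not, and the bar is the list's median. Stress response genes lie above 0 (median 0.40) and cholesterol genes below 0 (median -0.31), each with all members on 1 side.

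On transcripts of the respiratory chain and of ribosomal proteins, corticosterone replicate 2 stood apart from the other treated libraries. Mitochondrial transcripts made up 3.95 ± 0.0499% of counts in controls and 3.54 ± 0.252% with corticosterone (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest possible), with 3.52%, 3.80% and 3.30% in corticosterone replicates 1, 2 and 3. As a list they fell (camera, adjusted p = 0.000495), but not with an estimated correlation (camera, adjusted p = 0.517 with an estimated correlation) or after quantile normalization (camera, adjusted p = 0.685). Single transcripts passed in 0 of 15 cases in edgeR (8 at an unadjusted p under 0.05), in 3 with DESeq2, in 0 with limma and in 12 in edgeR without corticosterone replicate 2. The lowest p belonged to mt-Nd4l (-0.17), mt-Nd5 (-0.19), mt-Atp8 (-0.21) and mt-Cytb (-0.21), and the first 3 were the ones lower adjusted over the list alone. The counts of mt-Nd5 are uncertain for overlap with the opposite strand. Of 24 nuclear-encoded respiratory chain genes, Cox7a2 fell (-0.39), also over the list alone, and 23 did not pass, among them Sdhd (-0.17) and Ndufa4 (-0.26), while 16 fell without corticosterone replicate 2. That list passed (camera, adjusted p = 0.00272), but not with an estimated correlation (camera, adjusted p = 0.641 with an estimated correlation), and the call of Cox7a2 was lost without each library but corticosterone replicate 2 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.142, without corticosterone replicate 1). The 30 ribosomal protein genes did not pass as a list (camera, adjusted p = 0.0615). None of them passed singly or at an unadjusted p under 0.05 in edgeR, and 0 passed with DESeq2 and with limma, but 24 fell in edgeR without corticosterone replicate 2. Log2 fold changes over all libraries were -0.11 for Rps4x, -0.14 for Rpl11, -0.12 for Rps9 and -0.083 for Rpl7. Their mean log2 level relative to controls was -0.15, 0.14 and -0.23 in corticosterone replicates 1, 2 and 3.

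**Figure D3:**
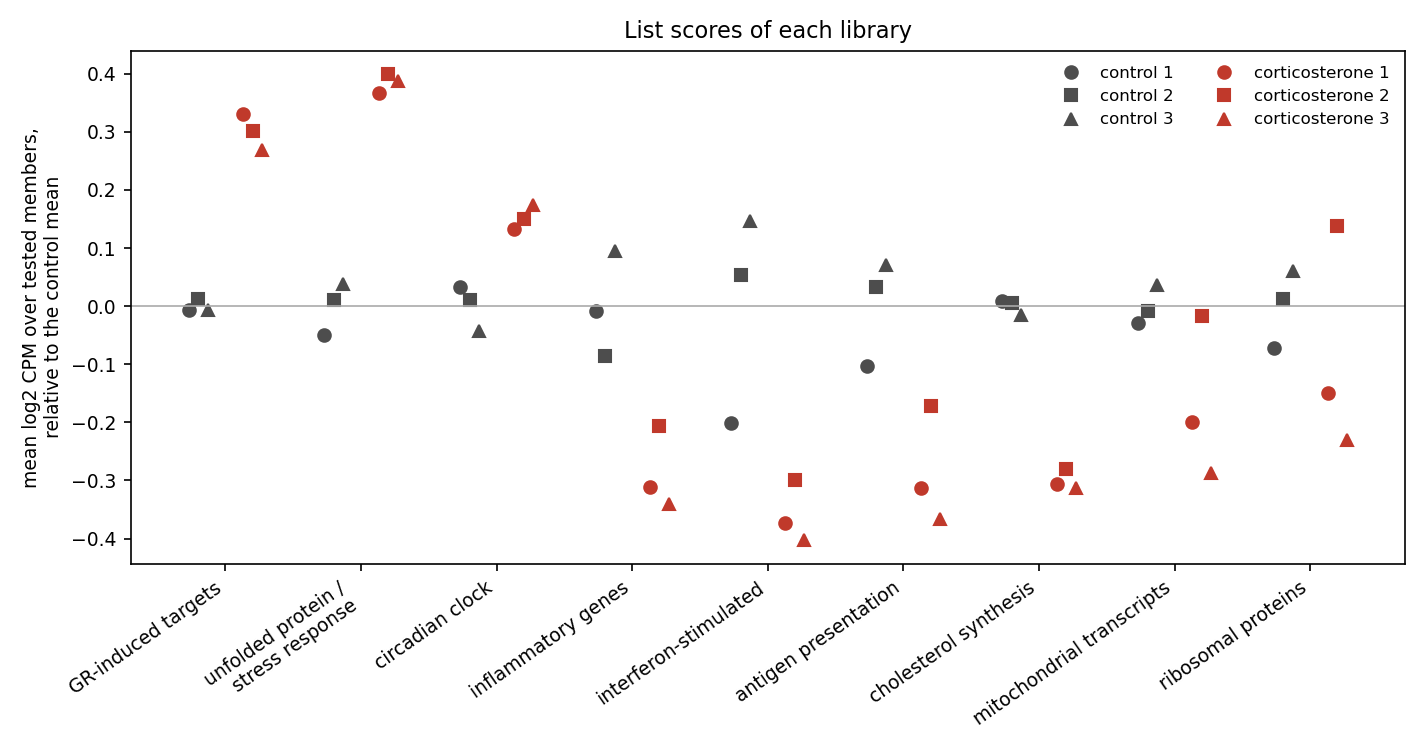
Mean log2 CPM over the tested members of 9 gene lists in each library, relative to the mean of the controls. Each point is 1 library. Corticosterone replicate 2 lies with the other treated libraries for receptor targets, stress response and cholesterol synthesis, and above them for ribosomal proteins (0.14 against -0.15 and -0.23).

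Of 28 G1/S and DNA replication genes, Myc rose (0.35), Pcna, the replication clamp, fell (-0.25), and 26 did not pass, with 14 lower and 1 higher, Myc, adjusted over the list alone, among them the helicase subunit Mcm3 (-0.24) and E2f1 (-0.29). Without corticosterone replicate 2, 16 members fell and 2 rose. As a list they fell (camera, adjusted p = 5.04e-05), but not with an estimated correlation (camera, adjusted p = 0.107 with an estimated correlation). The calls of Myc and Pcna were lost without control replicates 1, 2 or 3 or corticosterone replicate 1, and that of Pcna also without corticosterone replicate 3 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0909 and 0.19, both without control replicate 2). None of 27 G2/M genes passed in edgeR (5 at an unadjusted p under 0.05), against 2 with DESeq2 and 0 with limma, but without corticosterone replicate 2 edgeR called 2 higher and 5 lower, and the list did not pass (camera, adjusted p = 0.861). The lowest p were those of Hmmr (0.22), Top2a (-0.14), the mitotic kinase Cdk1 (-0.20) and Cenpf (0.13). Of 25 immediate early genes, Klf6 (0.82), Klf4 (0.47), Atf3 (0.43), Myc (0.35) and Fosl1 (0.34) rose and Ier3 fell (-0.47), Klf4 and Fosl1 being chosen after their values were seen, with 9 changed adjusted over the list alone and 7 higher and 3 lower without corticosterone replicate 2. That list passed (camera, adjusted p = 0.0044), but not with an estimated correlation (camera, adjusted p = 0.29 with an estimated correlation). All 6 calls were lost without control replicate 2 and without corticosterone replicate 1, all but that of Klf6 without control replicates 1 and 3, and that of Klf4 without corticosterone replicate 3, with adjusted p up to 0.216 (edgeR quasi-likelihood, Benjamini-Hochberg; Fosl1 without control replicate 2). Fosl1 and Top2a overlap genes on the opposite strand.

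The laminin chains Lama3 and Lamb3, parts of the basement membrane that anchors epithelial cells, rose by 1.15 (62.7 ± 9.10 to 139 ± 16.9 CPM) and 0.51 on the log2 scale. In the list of collagens and extracellular matrix, with 30 tested members, Lox (lysyl oxidase, 0.51) also rose, while Nid1 (nidogen-1, -0.95), Tnc (tenascin C, -0.35) and Sparc (-0.33) fell, Nid1 and Tnc being chosen after their values were seen. Adjusted over the list alone 11 members changed, and without corticosterone replicate 2 7 rose and 4 fell. The list passed (camera, adjusted p = 0.0451), but not with an estimated correlation (camera, adjusted p = 0.521 with an estimated correlation). It was lost without control replicate 2 (adjusted p = 0.223), corticosterone replicate 1 (0.0627) and corticosterone replicate 3 (0.0796), all by camera. The calls of Lama3 and Lamb3 held without each library, and those of Lox, Nid1, Tnc and Sparc were lost without control replicates 1, 2 or 3 or corticosterone replicate 1, and all but that of Sparc without corticosterone replicate 3, with adjusted p up to 0.222 (edgeR quasi-likelihood, Benjamini-Hochberg; Tnc without corticosterone replicate 1). Of 24 epithelial junction genes, the plakophilin Pkp1 rose (0.45), and Dsp (desmoplakin, 0.46) was the second member higher adjusted over the list alone, while Cldn1 (claudin-1, 0.93) and Esrp1, a splicing regulator (0.18), did not pass. Of these genes 5 rose and 1 fell without corticosterone replicate 2. That list passed narrowly (camera, adjusted p = 0.046), not with an estimated correlation (camera, adjusted p = 0.18 with an estimated correlation), and not without control replicate 1 (0.0607), control replicate 2 (0.0504), corticosterone replicate 1 (0.0879) or corticosterone replicate 2 (0.055), all by camera. Pkp1 lost its call without each library but corticosterone replicate 2 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.214, without corticosterone replicate 1). The counts of Lama3, Lamb3, Lox, Tnc and Dsp are uncertain for overlap with the opposite strand.

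The circadian clock list had 18 tested members, of which 4 rose, 3 fell and 11 did not pass, with 11 changed adjusted over the list alone and 7 higher and 4 lower without corticosterone replicate 2 (camera, adjusted p = 6.94e-05, and adjusted p = 0.0523 with an estimated correlation). Beside Per1, Arntl (BMAL1, the activator of the clock) rose by 0.62, Nfil3, a repressor of D-box genes, by 0.61 and Ciart, a repressor of CLOCK and BMAL1, by 0.55. Dbp, an activator of D-box genes, fell by 0.81 and Bhlhe40, a repressor that binds E-boxes, by 0.33, both chosen after their values were seen. The calls of Per1 and Nfil3 held without each library in turn, and that of Arntl was lost without control replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0671). Those of Ciart, Dbp and Bhlhe40 were lost without control replicates 1 or 2 or corticosterone replicate 1, those of Dbp and Bhlhe40 without control replicate 3, and that of Dbp without corticosterone replicate 3, with adjusted p up to 0.151 (edgeR quasi-likelihood, Benjamini-Hochberg; Dbp without control replicate 2). The list did not pass in limma without a filter (camera, adjusted p = 0.0815) or with library weights (camera, adjusted p = 0.085). Ciart, Dbp and Bhlhe40 overlap genes on the opposite strand.

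Targets of YAP/TEAD and TGF-beta went in both directions and did not pass as a list (camera, adjusted p = 0.145, 23 tested members), though they passed, below 0, with GC and length offsets and with the ribosomal protein score as a covariate. Ccn2 (0.84) and Tead4 (0.64) rose and Ltbp2 (-0.56), Ankrd1 (-0.55), Ccn1 (-0.49) and Bhlhe40 (-0.33) fell, with 9 changed adjusted over the list alone and 5 higher and 7 lower without corticosterone replicate 2. Ccn2 and Ccn1 encode related matricellular proteins, and their calls, with those of Ltbp2 and Ankrd1, held without each library in turn. Ccn2 is also counted among the glucocorticoid receptor induced targets that rose. Tead4 and Bhlhe40, chosen after their values were seen, lost their calls without control replicates 1, 2 or 3 or corticosterone replicate 1, and Tead4 also without corticosterone replicate 3 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.162 and 0.114, both without control replicate 2). The epithelial-mesenchymal transition list had a median of 0.03, a mean of 0.02 and a camera direction below 0 (adjusted p = 0.898), and of its 26 tested members Lox rose and S100a4 (-0.51) and Sparc fell, also adjusted over the list alone (4 higher and 4 lower without corticosterone replicate 2), each lost without control replicates 1, 2 or 3 or corticosterone replicate 1 and, for Lox and S100a4, corticosterone replicate 3 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.15, Sparc without corticosterone replicate 1). Mmp14, a membrane protease, had a log2 fold change of -0.15 that did not pass. Among 16 tested metallothioneins, lipocalin and acute phase genes, Mt2 (0.99) and Lbp rose, and Slc39a14 (0.60) was the third member higher adjusted over the list alone, while Il6ra (-0.26) did not pass and 4 members rose and 1 fell without corticosterone replicate 2 (camera, adjusted p = 0.00335, and adjusted p = 0.107 with an estimated correlation). Lbp had 0 counts in controls and 14, 26 and 21 with corticosterone, at least 20.4-fold higher (floor of 3 counts over the group), and the median of the list was 0.20 with the fitted value and with that bound. Mt2 lost its call without control replicates 1, 2 or 3 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.082, without control replicate 2) and Lbp without each library but corticosterone replicate 2 (highest 0.105, without corticosterone replicate 1). Ccn2, Ltbp2, Tead4, Bhlhe40 and Mt2 overlap genes on the opposite strand.

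Other genes with the largest changes at a mean of at least 5 FPKM were Dhrs9, a short-chain dehydrogenase, which rose by 1.70 (17.5 ± 2.34 to 56.9 ± 11.4 CPM), Tent5b by 1.19, the MAP kinase phosphatase Dusp7 by 1.12 (94.4 ± 3.72 to 205 ± 5.11 CPM), the metalloprotease Adam12 by 1.03, Sh2d5 by 0.94 and S100a7a by 0.89. Those that fell were Spn (CD43) by 1.06, the carbonyl reductase Cbr2 from 11.5 to 5.76 CPM, and Spry1, an inhibitor of receptor tyrosine kinase signalling, by 0.85. S100a7a lost its call without control replicates 1, 2 or 3 or corticosterone replicate 1 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.103, without control replicate 2) and Cbr2 without corticosterone replicate 1 (0.0546), and the other 7 calls held without each library. Of the most abundant genes that changed, Odc1, which makes the first polyamine, went from 928 ± 16.7 to 736 ± 23.3 CPM (log2 fold change -0.33) and Mtap, which recycles methionine, from 864 ± 15.9 to 716 ± 22.8 CPM (-0.27), both lost without control replicates 1, 2 or 3 or corticosterone replicate 1, and that of Mtap also without corticosterone replicate 3 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0876 and 0.166, both without corticosterone replicate 1). Spry1 and Mtap overlap genes on the opposite strand.

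None of 11 tested immune cell markers passed in edgeR, at an unadjusted p under 0.05 or with DESeq2, and 0 of the 9 that limma tested passed (camera, adjusted p = 0.52), but the list passed without corticosterone replicate 1. S100a9 had a log2 fold change of 0.73, S100a8 of 0.50, Tyrobp of 0.41 and Cd14 of -0.16, and the first 2 turned to -0.05 and -0.04 with library weights. None of 10 fibroblast markers passed in edgeR (1 at an unadjusted p under 0.05), 1 with DESeq2 and 0 of the 4 that limma tested (camera, adjusted p = 0.362), but the list passed without control replicate 3, and the lowest p were those of Postn (0.30), Fap (-0.76), Col1a2 (-0.10) and Col3a1 (0.38). Endothelial markers had 3 tested members, of which Pecam1 (1.24 to 0.62 CPM) was lower adjusted over the list alone and with DESeq2, while Egfl7 (-0.18) and Vwf (0.15) did not pass. Erythroid markers had 1, Alas2 (0.33, not passing, and -0.09 without corticosterone replicate 3). The 1 tested adipocyte marker, Fabp4, a fatty acid binding protein also made by other cells, rose from 0.555 ± 0.156 to 2.87 ± 0.236 CPM (log2 fold change 2.36), and its call held without each library in turn. None of 12 reference genes passed in edgeR (3 at an unadjusted p under 0.05), 1 with DESeq2 and 0 with limma (camera, adjusted p = 0.398), but 4 fell in edgeR without corticosterone replicate 2 and 4 with the ribosomal protein score as a covariate, with log2 fold changes of -0.22 for Ppia, -0.15 for Tuba1b, -0.13 for Gusb and -0.09 for Actb. None of 11 replication-dependent histone genes passed in edgeR, at an unadjusted p under 0.05 or with DESeq2, and 0 of the 2 that limma tested passed (camera, adjusted p = 0.97), and their median (0.06) and mean (-0.02) differed in sign (H2ac18 1.17, H2ac4 -0.83, H2bc4 -0.17, H1f2 0.12). None of 20 genes of the mammary lineage passed in edgeR (10 at an unadjusted p under 0.05), 4 with DESeq2 and 0 of the 13 that limma tested (camera, adjusted p = 0.97, median -0.08, mean 0.04), but edgeR called 3 higher and 4 lower without corticosterone replicate 2. Adjusted over that list alone 5 passed: Trp63 (1.82), Sox9 (0.37), Erbb3 (0.32, chosen after its value was seen), Krt14 (-0.33) and Kit (-1.15).

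Over 4596 annotation terms that the deposited table attaches to genes, 145 passed with the preset correlation (camera), 35 up and 110 down. Those with the lowest p in each direction were cholesterol biosynthesis (10 of 24 genes lower, median log2 fold change -0.30; camera, adjusted p = 1.19e-12) and aminoacylation of transfer RNA (12 of 33 higher, median 0.19; camera, adjusted p = 7.46e-10). Further terms below 0 were steroid synthesis and metabolism, guanylate-binding protein and interferon-beta terms, oxidative phosphorylation and the phagosome pathway of antigen presentation. Further terms above 0 were the multienzyme complex of transfer RNA synthetases, the unfolded protein response, dual-specificity MAP kinase phosphatases and the response to light, which holds Per1. With an estimated correlation 0 terms passed (camera, 132 at an unadjusted p under 0.05, lowest adjusted p = 0.975).

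All 487 changed genes had groups that did not overlap, as had 22.2% of all tested genes, against 10% by chance with 3 against 3. The median absolute log2 fold change of changed genes was 0.51, and 63 changed by at least 1 on the log2 scale, 40 higher and 23 lower. The count fell without any library but corticosterone replicate 2, without which it rose. It was 166, 88 and 160 without control replicates 1, 2 and 3. Without corticosterone replicates 1, 2 and 3 it was 123, 3670 and 239. Leaving out a library also lowers the power of the test. A lost call therefore does not by itself show that a gene rested on that library. Of 96 changed genes under the naming rule or chosen after their values were seen, 36 kept their call without each library in turn, 5 lost it once and 55 more often.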

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

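The library weights, the GC and length offsets, the covariate, and terms with an estimated correlation were tests chosen only after the result was seen. Against 487 changed genes (234 higher, 253 lower) in edgeR, limma on log2(FPKM + 1) without a filter gave 260 (135 higher, 125 lower) and edgeR without a low count filter 211 (112 higher, 99 lower). Limma on TPM gave 366 (202 higher, 164 lower), with more higher than lower genes. The replicate block gave 237 (130 higher, 107 lower), of which 226 were among the 487. DESeq2 gave 1293 (629 higher, 664 lower), library weights 4724 (2340 higher, 2384 lower), GC and length offsets 1144 (582 higher, 562 lower) and the ribosomal protein score as a covariate 2403 (1209 higher, 1194 lower). With an absolute log2 fold change of at least 1 the count was 63, at an adjusted p under 0.01 it was 144 and at an unadjusted p under 0.05 it was 2944 (edgeR quasi-likelihood, Benjamini-Hochberg). The other limma settings, the filter on mean FPKM and DESeq2 size factors gave 433 to 537 genes, TPM apart. Every one of the 487 genes kept its sign in each setting that tested it, which follows largely from their groups not overlapping.

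Leaving out 1 library moved the count in either direction. Without control replicates 1, 2 and 3 it was 166, 88 and 160, and without corticosterone replicates 1, 2 and 3 it was 123, 3670 and 239. Higher genes ranged from 60 (without control replicate 2) to 1884 (without corticosterone replicate 2) and lower genes from 28 to 1786 for the same libraries. Of the 487 calls, 85 remained without control replicate 2 and all 487 without corticosterone replicate 2, and 82 remained in all 6 cases.

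Of 16 lists past the threshold, 5 passed with an estimated correlation and 12 with fry, and 14 to 17 lists passed without each library in turn. The extracellular matrix list was lost in 17 of 22 settings (camera, adjusted p from 0.000379 to 0.315), epithelial junctions in 14 (camera, adjusted p from 0.00859 to 0.345), metallothioneins in 8 (camera, adjusted p from 0.000429 to 0.103), the circadian clock in 2 and mitochondrial transcripts in 1. The other 11 lists passed in all 22. Of 13 lists not past the threshold, 10 changed direction in at least 1 setting, with adjusted p of at least 0.345 (camera). Ribosomal proteins passed as a list in 10 settings: 5 of limma on log2 FPKM (pseudocounts 1 and 0.5, no filter, no trend, robust), no low count filter, the replicate block, library weights, and without control replicate 1 or corticosterone replicate 2. YAP/TEAD and TGF-beta targets passed with GC and length offsets and with the covariate, fibroblast markers without control replicate 3, and immune cell markers without corticosterone replicate 1. The 145 terms became 80 with quantile normalization, 234 with library weights and 0 with an estimated correlation. Without control replicate 3 there were 70, and without corticosterone replicates 1, 2 and 3 there were 69, 360 and 85.

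Signs of named genes that did not pass turned in some settings. Nr3c2 went to -0.034 without control replicate 3, -0.22 without corticosterone replicate 1 and 0.29 without corticosterone replicate 3. Hsd11b1 went to -0.21 without corticosterone replicate 2, -0.13 with library weights and 0.24 without corticosterone replicate 3. Alas2 went to -0.093 without corticosterone replicate 3, -0.25 with the covariate and 0.72 without corticosterone replicate 2. Cenpf went to -0.013 with GC and length offsets, Rps4x to 0.039 with quantile normalization, and S100a9 and S100a8 to -0.046 and -0.036 with library weights. No named gene that changed turned its sign, which was unlikely for genes whose groups did not overlap.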

Other observations

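Single genes of lists that did not pass also changed. In the list of apoptosis and p53 targets (28 tested members, median 0.01, mean -0.03, camera direction below 0, adjusted p = 0.979), the survival gene Bcl2l1 (0.45) and Trp53inp1 (0.39) rose and the death receptor Fas (-1.21) fell, with 11 changed adjusted over the list alone and 6 higher and 6 lower without corticosterone replicate 2. The call of Fas held without each library in turn, that of Bcl2l1 was lost without control replicate 2, and that of Trp53inp1 without each library but corticosterone replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p up to 0.216, Trp53inp1 without control replicate 2). Trp53inp1 was chosen after its value was seen. Bcl2l1 is also counted among the glucocorticoid receptor induced targets that rose. Among 28 oxidative stress and ferroptosis genes (median -0.04, mean 0.01, camera direction above 0, adjusted p = 0.75), Chac1 (0.80) and the cystine transporter Slc7a11 (0.72) rose and the iron exporter Slc40a1 (-0.66) fell, with 8 changed adjusted over the list alone, a log2 fold change of 0.32 for Hmox1, which did not pass over all genes, and 8 higher and 9 lower without corticosterone replicate 2. Slc7a11 lost its call without control replicates 1, 2 or 3 or corticosterone replicate 1, and Slc40a1 without each library but corticosterone replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p up to 0.149, Slc40a1 without control replicate 1).

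In the Wnt and ROR1 list (20 tested members; camera, adjusted p = 0.97), the receptor Ror1 rose from 1.89 to 4.58 CPM (log2 fold change 1.27) and the secreted inhibitor Sfrp1 fell (-0.51), with 3 changed adjusted over the list alone, Wnt7b (-0.21) among them and Nkd2 (0.58) not, and 3 higher and 3 lower without corticosterone replicate 2. Of 31 glycolysis and hypoxia genes (camera, adjusted p = 0.898), Ndrg1 (0.49) rose and the aldolase Aldoc (-0.51) fell, with Car9 (-0.44) and Vegfa (0.33) also past the threshold over the list alone, 4 in all, and 5 higher and 7 lower without corticosterone replicate 2. Ndrg1 kept its call without each library, and Ror1, Sfrp1 and Aldoc kept theirs only without corticosterone replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p up to 0.176, Sfrp1 without corticosterone replicate 1). Ndrg1, Car9, Wnt7b and Nkd2 overlap genes on the opposite strand. Among the genes with 0 counts in all controls, 4 chosen after their values were seen were Hoxc8, a homeobox gene (at least 11.4-fold higher), Cyp4f18, a fatty acid hydroxylase (17.4), Mmp16, a membrane protease (14.4), and Gm16325 (25.1), with a floor of 3 counts over the group. All 4 were called in edgeR and lost their call without each library but corticosterone replicate 2 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.207, Hoxc8 without corticosterone replicate 1). Cyp4f18 and Gm16325 overlap genes on the opposite strand.

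Corticosterone replicate 2 stood apart from the other treated libraries, and the tests for a mislabelled control and for a mixture were chosen only after the result was seen. On 14 receptor targets called without it, its median position was 0.945, with 0 at the control mean and 1 at the mean of corticosterone replicates 1 and 3, so a mislabelled control is unlikely. Its position on the receptor targets was 0.773 above that on the other genes called without it (median 0.172, permutation test over genes, 100000 resamples, two-sided p = 0.00015, smallest possible 1e-05). The prediction was that a mixture with control RNA would put both sets at 1 common position. Positions were taken on log2 values, where the position of a mixture also varies with a gene's fold change and direction. The prediction was therefore not exact. Genes do not vary independently, so this p does not measure the spread between libraries. The other genes were called on corticosterone replicates 1 and 3, whose shared deviations could lower their position, so the gap alone does not exclude a mixture. With GC and length trends taken out the count over 6 libraries was 1144, against 2727 without the library, so that bias could account for only part of the difference. The fitted trends had SDs over genes of 0.0667, 0.0864 and 0.115 in corticosterone replicates 1, 2 and 3. Its positions were not split cleanly by list: -0.68 for ribosomal proteins, -0.12 and 0.053 for nuclear and mitochondrial respiratory chain genes, 0.069 for steroid receptors and corticosteroid metabolism, 0.475, 0.532 and 0.655 for antigen presentation, G1/S and interferon genes, and 0.907, 1.12 and 1.15 for cholesterol, inflammatory and stress response genes, and no biological cause was tested.

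The rise of stress response genes and the fall of cholesterol genes was weighed against bias of the libraries, and the covariate test was chosen only after the result was seen. With GC and length offsets, 27 of 27 called members (16 and 11) kept their call and sign, as did 470 of all 487 changed genes. With the ribosomal protein score as a covariate 27 of 27 did so too, as did all 487 changed genes. The score varied mostly among treated libraries (-0.23 to 0.14, against -0.07 to 0.06 in controls), and 2403 genes were called with it. Since no changed gene lost its call, the covariate test cannot tell whether RNA composition contributed. Both tests also ran on genes picked by the main call. A first test, the position of corticosterone replicate 2 on the called members, was replaced by the covariate after its result was seen, because it ran on genes picked by the call and on 1 library.

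Of 25 genes that rose from under 1 CPM in controls, 3 (12%) had another raised gene on the same strand within 50 kb, against 74 of 4054 other genes at that level (1.83%; Fisher's exact test, two-sided p = 0.011). A further test, chosen only after the result was seen, took raised genes upstream alone: 2 of 25 (8%) had one, against 45 of 4054 (1.11%; Fisher's exact test, two-sided p = 0.0329). Uox and Gm16325 were each other's neighbour in the first test, so the genes counted were not independent. In the second, Kif17 counted only because it starts at 138250435, just after the start of Sh2d5 (138250403). Neither p-value can therefore decide the question. Transcription running on from a raised gene could account for Kif17, which overlaps Sh2d5, and Gm16325, which lies 9.63 kb downstream of Uox. Shared regulation would give the same 8%. How reads were assigned where Kif17 and Sh2d5 overlap is not given in the sources used here. Such transcription could not account for Uox, whose raised neighbour lies downstream. Uox (urate oxidase) rose 8.11-fold and Kif17, a kinesin, by 2.10 on the log2 scale, both chosen after their values were seen, and Uox overlaps Dnase2b on the opposite strand. The call of Uox held without each library, and that of Kif17 was lost without each but corticosterone replicate 2 (highest edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.183, without corticosterone replicate 1). The other genes of the 25 had no such neighbour.

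The 10 splits of the 6 libraries into 3 and 3 are too few for a p under 0.05. The real split gave 487 changed genes against at most 2 in another, and 234 higher and 253 lower against at most 1 each. It gave 16 lists against 4 to 9 in the others, so 1 split of 10 was as large for each of these counts. Lists thus passed camera at the preset correlation also in splits that mixed treated and control libraries. For terms 3 splits of 10 were as large: the real one gave 145, control replicate 1 with corticosterone replicates 1 and 3 against the rest gave 328, and control replicates 1 and 3 with corticosterone replicate 2 against the rest gave 200. Both set corticosterone replicate 2 against the other treated libraries.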
